A study of Arabidopsis thaliana with 7 samples.

How the data were processed

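RNA was sequenced from 10-day-old Arabidopsis thaliana seedlings of the Col-0 background, grown at 22 °C with 16 h of light and 8 h of darkness a day. Per the labels, 2 libraries came from wild-type (WT) seedlings and 2 from the hon45 mutant, in which HON4 and HON5 are affected. Another 3 samples of the series are chromatin immunoprecipitations with an antibody to the Myc tag, 1 from WT and 2 from plants carrying HON5-Myc; they were not analysed here.

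Gene counts were deposited as raw whole-number counts per gene, not normalized, with one column per library, and replicates were not pooled. A second kind of file, one per library, held FPKM values (fragments per kilobase of transcript, scaled to the mapped total) deposited by the authors, per the file headers, with a locus for each gene. The submitters' processing notes list HISAT2, Bowtie2, edgeR, deepTools and the TAIR10 build, with no roles or versions. The program that counted reads, the annotation it used and the program that made the FPKM values are not given in the sources used here. The count table listed 32548 genes, of which 46 had no count in any library, and no plastid or mitochondrial gene. The FPKM files listed 33557 genes. Of the genes counted, 4571 had no FPKM value, and 5580 genes with an FPKM value had no row among the counts. A failed status in at least 1 library excluded 3 genes from the FPKM fits.

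How reads were assigned affects what a count means. The lncRNA gene AT2G08665 and the gene LHCB1.5 that lies across it had 759384 and 759372 counts in WT replicate 1, so reads in overlapping genes were counted for each of them. Among the 29226 tested genes, 9287 overlap another counted gene by RefSeq spans, and their values are uncertain for that reason; no source says that counting used the strand. Gene names, biotypes and overlaps came from a RefSeq gene table of the TAIR10.1 assembly, in which all 32548 identifiers of the count table were found. Printed coordinates are those of the FPKM files, on TAIR10, with 1 added to the start because these files count from 0. Where genes overlap, those files give 1 locus that spans them.

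Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr and libraries scaled by TMM, and hon45 was compared with WT by the edgeR quasi-likelihood test (glmQLFit and glmQLFTest) with group as the only term and 2 residual degrees of freedom. The p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are said to have risen or fallen. Standard errors (SE) of log2 fold changes are the absolute log2 fold change over the square root of the F statistic. Levels are CPM values, counts scaled to a common library size by the TMM-scaled totals, given as mean ± SD. Before the data were examined, 28 gene lists with 392 genes, the rule for naming genes, the tests and most alternatives were fixed. Each list was tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 28 lists; camera with an estimated correlation and fry were alternatives. The rule named HON4 and HON5, the tested members of the FLC clade and SVP with 6 floral promoters, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and both hon45 libraries on the same side of both WT libraries, and up to 4 called members of each list with the smallest p. Other genes are named as chosen after their values were seen.

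Alternatives were RLE size factors, library totals without TMM, looser and stricter count filters (5 CPM in 2 libraries), DESeq2 1.42.0, the edgeR exact test, the older quasi-likelihood method, limma-voom, a replicate block, each library left out in turn, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and limma-trend on log2(FPKM + 1) for genes at 1 FPKM or more in 2 libraries, with a pseudocount of 0.1 or no filter as further settings. A log2 change on the log2(FPKM + 1) scale understates the change of low genes. Leaving out 1 library leaves its genotype with 1 library, which lowers the power of the test. A call lost in such a fit does not by itself show that the change depends on the library left out. Chosen after the data were seen were fits without ribosomal RNA genes, without overlapping genes and without genes under 1 CPM, and 2 fits with a gene-length trend removed. For these, the length of each gene was taken as the length that its counts and FPKM together imply, as a median over libraries with at least 10 counts and an FPKM of at least 0.1. In each library, a natural spline with 4 degrees of freedom of the log2 CPM deviation on log2 length was fitted over 10048 protein-coding genes that overlap no other gene and have a mean of at least 5 CPM, and entered as an offset for the 25906 tested genes with a length. The other version fitted the spline on the 14676 such genes with a mean of at least 1 CPM. Calls under both versions had been seen before either was kept, and since they differ, both are given. After removal, Spearman's rho between length and log2 fold change was 0.0297 and 0.0217 over the genes each version was fitted on, and 0.233 over the genes from 5 CPM in the version fitted from 1 CPM.

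The 4 libraries had total counts of 53858439 and 63543079 in WT and of 59639582 and 58390911 in hon45, with TMM factors from 0.979 to 1.013. At this depth 1 CPM stands for more than 50 counts, and the precision was set by the spread between libraries, a biological coefficient of variation of 12.2%. Replicates differed beyond sampling noise, with a chi-square per degree of freedom of 22.1 for WT and 14.9 for hon45. No source says that the replicates came from separate batches of plants, so p-values measure the spread between these libraries. The tests were tested on simulated data for hon45 against WT. The quasi-likelihood test on 28869 genes recovered 49.3% of genes changed by 1.5-fold, 77.6% at 2-fold and 98.5% at 4-fold, and 8.5% of its calls were false. The list test on 28826 genes found 2 of 2 raised lists with the preset correlation, and 0 with an estimated correlation or fry. Only 2 lists were raised, too few to measure the power of any of these tests. Whether the preset correlation suits lists whose genes change together was not tested in this simulation. Lists that passed with the preset correlation but not with an estimated one are therefore uncertain. With a simulated length trend in hon45 against WT on 28856 genes, 93.5% of calls were false, against 7.8% once the trend was removed. That trend was linear, equal in both hon45 libraries and built on lengths known exactly. These rates do not carry over to the data, where lengths were estimated and the WT libraries differed in the trend.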

Results

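The transcriptomes of 10-day-old WT and hon45 seedlings were compared, with 2 RNA-seq libraries of each genotype and 53858439 to 63543079 counts per library. HON4 and HON5 encode proteins with a linker-histone-like globular domain and AT-hook motifs, which bind linker DNA and shape chromatin. The comparison asks which genes change where both genes are affected, with flowering time as the trait named in the title of the series. Without single mutants it cannot tell the part of HON4 from that of HON5.

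Transcripts of both mutated genes fell in hon45. HON5 (AT1G48620; TAIR10 chromosome 1, 17973697 to 17976389) went from 94.7 ± 4.29 CPM (SD, n = 2) in WT to 14.9 ± 1.39 CPM in hon45, a log2 fold change of −2.66 (SE 0.11, adjusted p = 3.09e-12 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). HON4 (AT3G18035; chromosome 3, 6169090 to 6171724) went from 102 ± 3.38 to 40.1 ± 1.3 CPM, a log2 fold change of −1.34 (SE 0.10, adjusted p = 5.42e-08 by the same test). Reads from both genes were thus still counted in hon45; the HON4 locus overlaps another gene, AT3G18030. The other 7 members of the HON and H1 family list, which holds the linker histones H1.1 to H1.3, HMGA and the telomere-repeat-binding proteins TRB1 to TRB3, had log2 fold changes from −0.15 to 0.20 and none was called. The list passed the list test as lower in hon45 (camera adjusted p = 2.79e-07, and 0.642 with an estimated correlation), but its median was 0.04 above 0 against a mean of −0.41. Without HON4 and HON5 its camera p was 0.496, unadjusted, and without hon45 replicate 1 the camera adjusted p of the whole list was 0.0522.

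**Figure D1:**
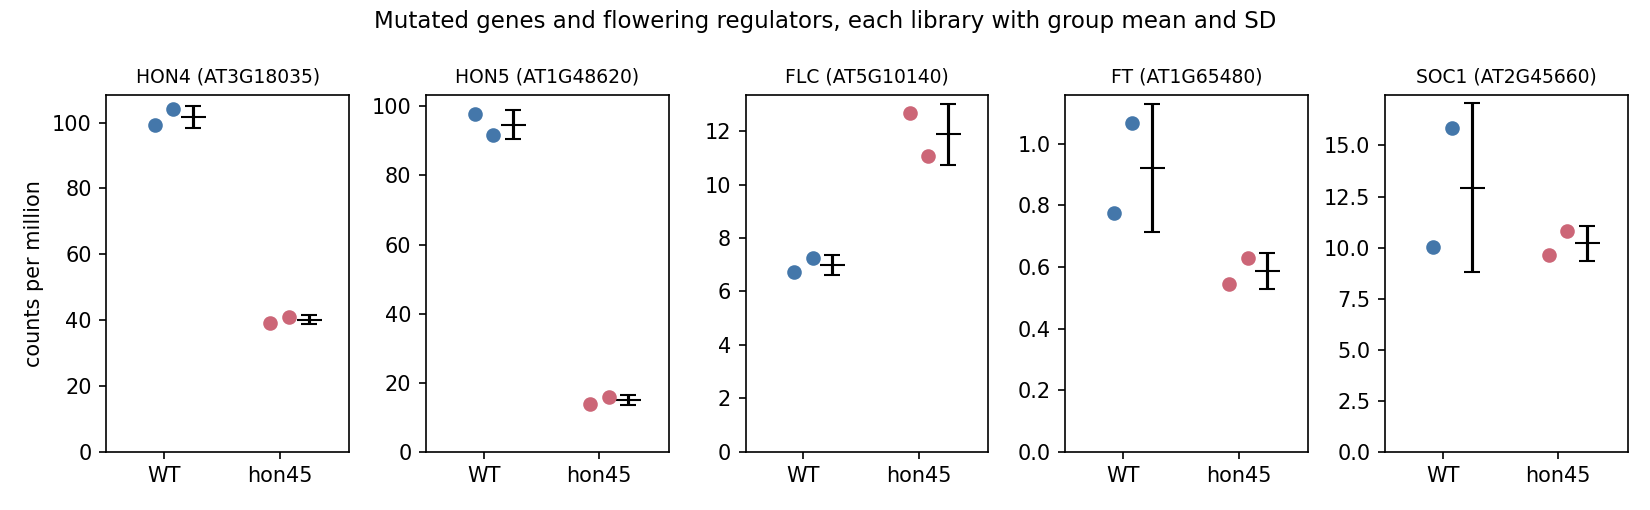
CPM of HON4, HON5, FLC, FT and SOC1 in WT and hon45 seedlings, on linear axes from 0. Points are single libraries, and the bars beside them are the group mean and SD (n = 2); HON5 lies at 94.7 CPM in WT against 14.9 CPM in hon45, and FLC at 6.98 against 11.9 CPM.

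FLC, the MADS-box repressor of flowering, was higher in hon45, and it was the called member of its clade. FLC (AT5G10140; chromosome 5, 3173497 to 3179448) rose from 6.98 ± 0.37 to 11.9 ± 1.15 CPM, a log2 fold change of 0.77 (SE 0.14, edgeR quasi-likelihood adjusted p = 0.00381). MAF5, an FLC relative, stood at 2.56 ± 0.31 against 4.19 ± 0.44 CPM, a log2 difference of 0.71 (SE 0.21) with an adjusted p of 0.066 in that test. The other relatives were closer to 0, with log2 differences of 0.23 for FLM, 0.18 for MAF2, 0.14 for MAF4 and −0.05 for MAF3, and SVP, the partner of FLC in repression, stood at −0.08. In the FLC clade and SVP list, 1 of 7 members rose, and 2 rose with p adjusted over the list alone; the list passed as higher (camera adjusted p = 0.025, and 0.642 with an estimated correlation). The camera adjusted p was 0.11 without WT replicate 1, 0.124 without hon45 replicate 2 and 0.222 without overlapping genes. FLC overlaps the lncRNA gene AT5G01675, whose reads cannot be told from those of FLC here. Without hon45 replicate 1 FLC stood at 0.70 (edgeR quasi-likelihood adjusted p = 0.0529), and without WT replicate 2 MAF5 passed at 0.84 (adjusted p = 0.0384 in that test). MAF5 also passed with RLE size factors (0.73, edgeR quasi-likelihood adjusted p = 0.0255), the edgeR exact test (adjusted p = 0.0331), a replicate block (edgeR adjusted p = 0.0487) and ribosomal RNA genes left out (edgeR adjusted p = 0.0412). On FPKM, 0.916 and 1.62 in WT against 4.55 and 4.09 in hon45, MAF5 passed at 1.25 (limma-trend adjusted p = 0.0383), but not with a pseudocount of 0.1 (1.74, adjusted p = 0.0577) or without a filter (adjusted p = 0.201).

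None of the 6 named floral promoters was called, at levels under 2 CPM except SOC1. FT, the mobile flowering signal, stood at 0.922 ± 0.21 CPM in WT and 0.588 ± 0.059 CPM in hon45, a log2 difference of −0.66 (SE 0.41, edgeR quasi-likelihood adjusted p = 0.427). SOC1, which integrates flowering signals, stood at 12.9 ± 4.13 against 10.2 ± 0.84 CPM, a log2 difference of −0.35 (SE 0.17, adjusted p = 0.277 in that test). SOC1 followed the WT libraries, at 10.0 and 15.9 CPM: without WT replicate 1 it fell by 0.63 on the log2 scale (adjusted p = 0.000719 in that test), and without WT replicate 2 its difference was 0.03. The meristem identity genes AP1 and LFY had log2 differences of −0.74 (SE 0.32) and −0.70 (SE 0.32), TSF of −0.35 and FUL of 0.14. Of the 19 tested floral promoters 0 rose and 0 fell, and 14 lay below 0; the list did not pass (camera adjusted p = 0.0968). AP1 and LFY had unadjusted p-values of 0.0324 and 0.0392 (n = 2 per genotype), with both hon45 libraries below both WT libraries, and adjusted p-values of 0.226 and 0.247 in the edgeR quasi-likelihood test. The direction of AP1 is uncertain, since its FPKM was 0.081 and 0.104 in WT against 0.147 and 0.113 in hon45, and its counts and FPKM imply a length of 8302 bases for a locus from 25982330 to 25986313.

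Regulators of FLC shifted little one by one. In the list of FLC repressors, such as the autonomous-pathway and Polycomb genes, 0 of 18 were called over all genes and 2 rose with p adjusted over the list alone, the splicing factor PRP8 at 0.35 and the histone methyltransferase CLF at 0.46 on the log2 scale. Of the 18, 16 lay above 0 and the list passed as higher (camera adjusted p = 0.00122, and 0.642 with an estimated correlation). These genes are long, with a median length of 2290 bases, and with a gene-length trend removed the camera adjusted p was 0.125 where the trend was fitted on genes from 5 CPM and 0.0104 where it was fitted on genes from 1 CPM. Of the 18 FLC activators 0 were called and 13 lay above 0 (camera adjusted p = 0.0545, and 0.642 with an estimated correlation). The FLC activators passed as higher with RLE size factors (camera adjusted p = 0.0399), no count filter (0.0296), ribosomal RNA genes left out (0.0472), overlapping genes left out (0.0288) and without WT replicate 1 (0.00837). In the other camera fits with the preset correlation they had 0.0522 to 0.456. TOE3, an AP2-type floral repressor, rose by 0.56 on the log2 scale, the 1 called member among 9 in its list (camera adjusted p = 0.876). SEP4, which acts in floral organ identity, rose by 0.79, the 1 called among 10 (camera adjusted p = 0.613), while the other 9 lay below 0 and the list median was −0.415. Neither TOE3 nor SEP4 passed without hon45 replicate 2 (edgeR quasi-likelihood adjusted p = 0.378 and 0.247), nor SEP4 without WT replicate 1 (0.0566).

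Over all genes, 1199 of 29226 passed the test, 724 higher and 475 lower in hon45, with 5237 at an unadjusted p under 0.05 (edgeR quasi-likelihood). Most changes were small: 537 of the rises and 232 of the falls were under 1.5-fold, while 18 genes rose and 89 fell by at least 2-fold. In 1190 of the 1199 genes both hon45 libraries lay on the same side of both WT libraries. This held for 49.3% of all tested genes and for 33.3% by chance. Genes selected by a small p are apart in this way almost by construction, so the difference adds no support for the calls. Of 1156 called genes that have an FPKM value, 1132 changed in the same direction there and 11 in the opposite one. By overlap, 373 of the called genes share their locus with another counted gene. Genes that rose were long, with a median length of 2049 bases, and genes that fell were short, at 893 bases, against 1384 bases for tested genes. With the gene-length trend removed, 867 genes passed with the trend fitted on genes from 5 CPM, 395 higher and 472 lower, and 936 with it fitted on genes from 1 CPM, 609 higher and 327 lower. The share of rises was 60.4% in the test above, 45.6% and 65.1% in these fits and 73.3% with DESeq2, which called 776 higher and 283 lower. Without hon45 replicate 2, 119 genes passed, 37 higher and 82 lower. Without hon45 replicate 1, 435 passed, 184 higher and 251 lower, and without WT replicate 2, 3836 passed.

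Among genes with a mean of at least 5 CPM and hon45 libraries apart from WT, the largest falls came from a single locus on chromosome 1. MRD1 (AT1G53480), named for its lower expression in a methionine over-accumulating mutant, and the lncRNA gene AT1G07887 that overlaps it went from 39.5 ± 1.71 and 38.9 ± 1.98 CPM to 0.688 ± 0.057 and 0.445 ± 0.16 CPM, log2 fold changes of −5.84 (SE 0.16) and −6.45 (SE 0.18). HEI10, a meiotic crossover gene that shares this locus (19963047 to 19969757), was listed at −4.19, and its value is uncertain because of the overlap: its FPKM was 1.31 and 1.19 in WT and 0.776 and 0.427 in hon45. AT1G07887 had 2183, 2389, 20 and 32 counts in WT 1, WT 2, hon45 1 and hon45 2, close to the 2205, 2439, 44 and 37 of MRD1. It has no FPKM value, so its fall cannot be told from that of MRD1. After these and HON5 came AT1G36622 at −1.82, ICL (isocitrate lyase of the glyoxylate cycle; chromosome 3, 7652487 to 7656011) at −1.76 (SE 0.17), with 13.5 ± 2.82 against 3.99 ± 0.69 CPM, AT1G26240 at −1.69 and AT4G07820 at −1.43. All of these had edgeR quasi-likelihood adjusted p-values of at most 0.000152. The fall of AT1G26240 is uncertain, since its FPKM was at most 1.92 in WT and 0.765 in hon45, a log2(FPKM + 1) difference of −0.73 (limma-trend adjusted p = 0.119), and its counts and FPKM imply a length of 7928 bases for a locus from 9078140 to 9079576.

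The largest rises among such genes were those of the neighbouring genes AT4G13577 at 2.54 and AT4G13575 at 1.66 on the log2 scale, and of AT1G52100 at 1.81 (chromosome 1, 19383122 to 19385602), which went from 6.66 ± 0.93 to 23.4 ± 0.71 CPM. TIFY4A (AT4G14713), also named PEAPOD1 and known to limit leaf cell proliferation, rose by 1.42 (SE 0.21), with 4.70 ± 0.09 against 12.6 ± 5.22 CPM, and the lncRNA gene AT4G06215, which overlaps AT4G14710, by 1.37. The FPKM values of TIFY4A were 3.46 and 3.89 in WT and 4.05 and 3.6 in hon45 (limma-trend adjusted p = 0.845), so its rise in counts is uncertain. AT3G21950 rose by 1.26. TGG2, a myrosinase of glucosinolate breakdown, rose by 1.31 (SE 0.27) and GASA6, a gibberellin-regulated peptide gene, by 1.17 (SE 0.25), but their WT libraries lay far apart, at SDs of 19.3 and 8.83 CPM around means of 26.6 and 13.3 CPM. Without WT replicate 1 the rises of TGG2 and GASA6 were 0.725 and 0.624, and without WT replicate 2 they were 2.36 and 2.1 on the log2 scale. DESeq2 called neither TGG2 nor GASA6 (adjusted p = 0.29 and 0.305), and GASA6 did not pass without hon45 replicate 2 (edgeR quasi-likelihood adjusted p = 0.0919).

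Genes of salicylic acid defence were called in both directions, the lower one by CBP60G alone. WRKY70, a regulator of this pathway, rose by 0.85 (12.1 ± 3.39 to 22.0 ± 1.06 CPM) and the pathogenesis-related genes PR2 and PR5 rose by 1.03 and 0.77, while CBP60G, an activator of salicylic acid synthesis, fell by 0.50 on the log2 scale. In all, 4 of 21 members rose and 1 fell (5 and 2 with p adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.155). Without hon45 replicate 2, 1 rose and 0 fell, with WRKY70 at an edgeR quasi-likelihood adjusted p of 0.0635 and PR5 at 0.174. The fall of CBP60G is uncertain, since it lost its call under 10 of 21 alternatives. Among these were DESeq2 (adjusted p = 0.105), FPKM (limma-trend adjusted p = 0.151), library totals, and the looser and stricter count filters. Without hon45 replicate 1 and without hon45 replicate 2 it did not pass either, at log2 differences of −0.26 and −0.73. CYP81F2, of indole glucosinolate modification, fell by 0.78, the 1 called among 8 genes of tryptophan-derived defence metabolites (camera adjusted p = 0.739). ERF6 fell by 0.77, the 1 called among 20 genes of rapid wound and touch response, of which 3 fell with p adjusted over the list alone (camera adjusted p = 0.0504, and 0.751 with an estimated correlation). This wound and touch list passed as lower with library totals (camera adjusted p = 0.0453), the stricter filter (0.0411), overlapping genes left out (0.0132), genes under 1 CPM left out (0.042), and without WT replicate 2 (0.0132) or hon45 replicate 2 (0.00391). It had 0.467 without WT replicate 1 and 0.792 without hon45 replicate 1, and 0.0511 to 0.086 in the other camera fits with the preset correlation. Without hon45 replicate 1, CYP81F2 and ERF6 had edgeR quasi-likelihood adjusted p-values of 0.0791 and 0.0563, and without hon45 replicate 2 ERF6 had 0.144. Of 22 jasmonate genes and 5 aliphatic glucosinolate genes 0 were called (camera adjusted p = 0.858 and 0.0676), with 0 and 2 higher with p adjusted over the list alone.

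Of 11 chaperones of the endoplasmic reticulum 1 was called, and 9 lay above 0. SHD, the HSP90 of that compartment, rose by 0.70 (SE 0.10, 76.3 ± 9.06 to 124 ± 3.18 CPM, edgeR quasi-likelihood adjusted p = 0.000802), and 5 members rose with p adjusted over the list alone, among them ERDJ3B at 0.40 and the Hsp70 genes BIP2 at 0.36 and BIP1 at 0.32. The list passed as higher (camera adjusted p = 0.00114, and adjusted p = 0.719 with an estimated correlation). Without WT replicate 2, 7 of the 11 chaperones rose; without hon45 replicate 2, 0 were called and SHD stood at 0.68 (edgeR quasi-likelihood adjusted p = 0.0521). Of 13 heat shock genes 0 were called, and their list (camera adjusted p = 0.9) had a median of 0.03 but a mean of −0.11.

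Clock genes were called in small numbers. Of 10 morning genes PRR7, a repressor within the clock, rose by 0.62 (SE 0.10) and LNK1, a transcriptional coactivator, by 0.50 (SE 0.10), and 3 rose with p adjusted over the list alone. That list passed as higher (camera adjusted p = 0.025, and 0.642 with an estimated correlation), but with the gene-length trend removed the camera adjusted p was 0.151 (genes from 5 CPM) and 0.0907 (genes from 1 CPM), without WT replicate 1 it was 0.115 and without hon45 replicate 2 it was 0.124. Of 9 evening genes ELF3 rose by 0.52, and 2 rose with p adjusted over the list alone (camera adjusted p = 0.152). With the trend of genes from 5 CPM removed, neither LNK1 nor ELF3 passed (edgeR quasi-likelihood adjusted p = 0.053 and 0.116). Without hon45 replicate 2, PRR7, LNK1 and ELF3 had adjusted p-values of 0.0918, 0.274 and 0.266 in that test, without hon45 replicate 1 LNK1 and ELF3 had 0.0562 and 0.0969, and without WT replicate 1 ELF3 had 0.13.

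Among 19 root markers 5 fell and 0 rose, with 7 above 0; 7 fell with p adjusted over the list alone, and the list passed as lower (camera adjusted p = 0.00149, 0.642 with an estimated correlation, 0.166 without hon45 replicate 1). EXP18 and EXP7, root hair expansins, fell by 0.61 and 0.47, the tonoplast aquaporin TIP2;3 by 0.57, the root hair wall protein gene PRP3 by 0.52 and CASP1, of the endodermal Casparian strip, by 0.51 on the log2 scale. Of these 5, 0 passed without hon45 replicate 2 and 1 without hon45 replicate 1 (edgeR quasi-likelihood). PYK10, the abundant root beta-glucosidase, stood at 3272 ± 302 against 3878 ± 56.9 CPM (log2 difference 0.25, not called). MCM5, of the replicative helicase, rose by 0.62 (SE 0.14), the 1 called of 14 cell cycle and DNA replication genes, and 3 rose with p adjusted over the list alone; the list passed as higher (camera adjusted p = 0.00709, and 0.642 with an estimated correlation). MCM5 did not pass without hon45 replicate 1 or without hon45 replicate 2, but its log2 differences there were 0.61 and 0.67. With the length trend of genes from 5 CPM removed MCM5 did not pass either (0.48, edgeR quasi-likelihood adjusted p = 0.0703), and 0 of the 14 were called. Among 16 seed markers EM6 fell by 1.27 on the log2 scale (camera adjusted p = 0.31), at levels of 1.54 ± 0.064 and 0.637 ± 0.011 CPM. With any 1 library left out EM6 did not pass, but its log2 difference stayed between −1.31 and −1.23. Of 21 nuclear-encoded photosynthesis genes 0 were called (camera adjusted p = 0.0504). With the gene-length trend removed the list passed as higher (camera adjusted p = 0.0141 with genes from 5 CPM and 0.0218 with genes from 1 CPM). It also passed as higher with RLE size factors (camera adjusted p = 0.031) and no count filter (0.0217), but not with library totals (0.0672). For these genes the adjusted p was 0.811 with an estimated correlation, and without WT replicate 1 the camera adjusted p was 0.904 with a median of −0.03.

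**Figure D2:**
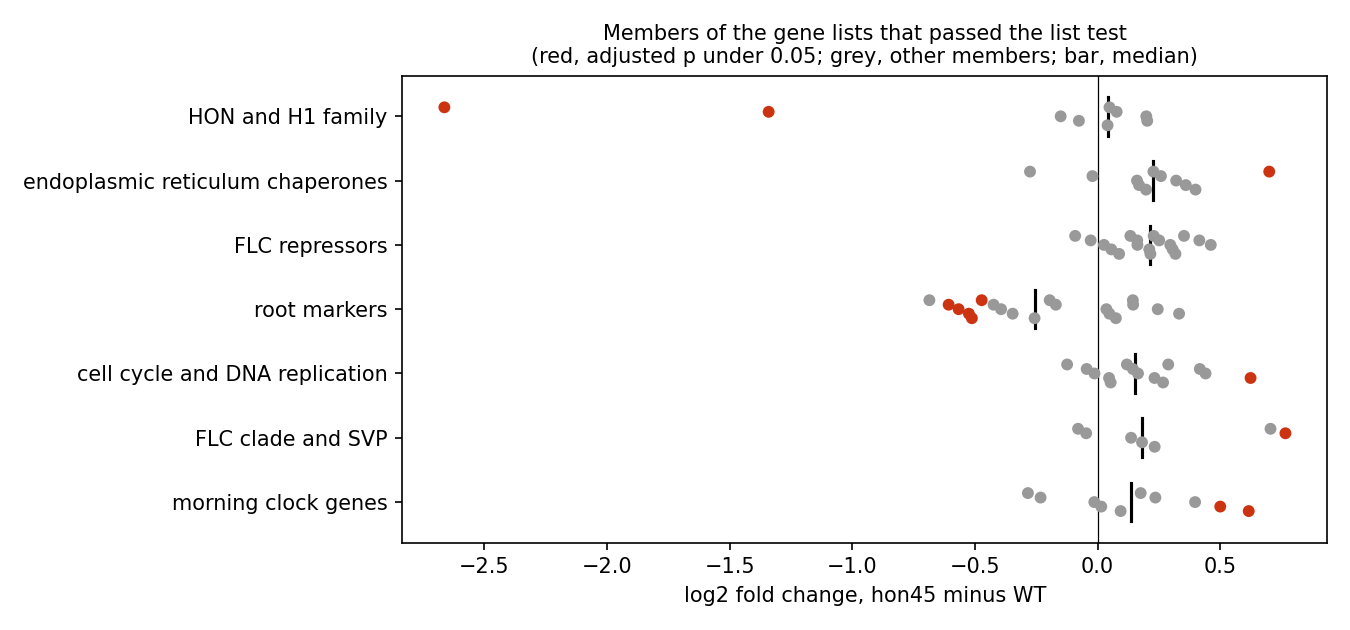
Log2 fold changes (hon45 minus WT) of the members of the 7 gene lists that passed camera with the preset correlation. Each point is a gene, red where its adjusted p was under 0.05, and bars are list medians; the HON and H1 family is split between HON5 and HON4, at −2.66 and −1.34, and 7 members between −0.15 and 0.20.

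In the remaining lists few genes were called. Of 17 flavonoid and anthocyanin genes 2 fell, the regulator MYB11 at −1.06 and CYP75B1 (flavonoid 3′-hydroxylase, AT5G07990) at −0.86 (54.7 ± 29.0 to 30.0 ± 4.03 CPM). The list did not pass (camera adjusted p = 0.0676). With RLE size factors it passed as lower (camera adjusted p = 0.0237), and with library totals it did not pass (0.103). This list followed the WT libraries: without WT replicate 1, 2 of its genes rose and 0 fell and it passed as higher (camera adjusted p = 0.0229), and without WT replicate 2, 0 rose and 10 fell and it passed as lower (camera adjusted p = 2.46e-11). Of 22 abscisic acid and cold genes NCED3, of abscisic acid synthesis, fell by 0.62 and the dehydrin gene RAB18 by 0.51 (camera adjusted p = 0.636). Among 12 phosphate starvation genes SPX1 rose by 0.46 and the transporter gene PHT1;4 fell by 0.68 (camera adjusted p = 0.395), with 2 higher and 3 lower with p adjusted over the list alone. Among 19 iron genes the ferritin gene FER4 rose by 0.44 and BHLH39, an activator of iron uptake, fell by 1.05 (camera adjusted p = 0.684), with 2 and 2 over the list alone. IAA2 rose by 0.44, the 1 called of 11 auxin response genes (camera adjusted p = 0.684). Of 18 gibberellin, 9 shade and 5 nitrate genes 0 were called (camera adjusted p = 0.876, 0.684 and 0.684), and the gibberellin list tested as higher with a mean of −0.03. Without hon45 replicate 2, none of NCED3, RAB18, SPX1, PHT1;4, FER4, BHLH39, IAA2, MYB11 and CYP75B1 passed (edgeR quasi-likelihood adjusted p from 0.0919 to 0.407). Without hon45 replicate 1, the same genes other than BHLH39 had 0.0523 to 0.221 in that test, and without WT replicate 1 NCED3, BHLH39, IAA2, MYB11 and CYP75B1 had 0.13 to 0.586. With the length trend of genes from 5 CPM removed, MYB11, CYP75B1 and BHLH39 had 0.06, 0.0584 and 0.0821 in that test, but their log2 differences stayed about as large (−1.07, −0.93 and −1). The log2 difference of CYP75B1 was −0.185 without WT replicate 1 and −1.32 without WT replicate 2. BHLH39 had 0.0655 without WT replicate 2, and DESeq2 did not call CYP75B1 (adjusted p = 0.404).

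The libraries were not alike in content. Hon45 replicate 2 held 1.224% of its counts in ribosomal RNA genes against 2.257 to 2.666% in the other libraries, 576 genes at 0 counts against 223 to 296, and 0.2438% of counts in genes with a mean under 1 CPM against 0.382 to 0.3916%. On the first principal component (58.5% of the variance) the libraries lay at −28.6 and −9.59 for WT and 11.5 and 26.7 for hon45. Gene length moved with genotype too: across 10048 genes, Spearman's rho between length and log2 fold change was 0.4, and genes are not independent replicates. These genes had means of at least 5 CPM. The same correlation was 0.24 for WT replicate 2 against WT replicate 1 and −0.00375 for hon45 replicate 2 against hon45 replicate 1. Over 14676 genes with means of at least 1 CPM the 3 correlations were 0.157, 0.149 and −0.224.

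**Figure D3:**
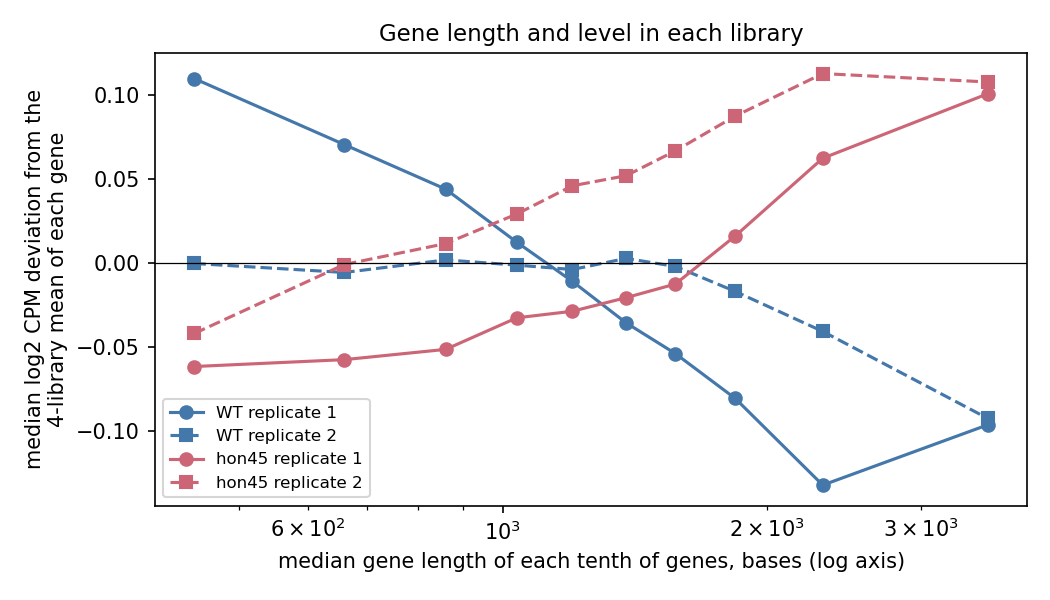
Median deviation of log2 CPM from the mean of each gene over the 4 libraries, for 10 groups of genes ordered by length (log axis, bases); lines are single libraries. In the tenth of shortest genes (median 445 bases) WT replicate 1 lies at 0.11 and the hon45 libraries at −0.06 and −0.04, and in the tenth of longest genes (3576 bases) the WT libraries lie at −0.10 and −0.09 and the hon45 libraries at 0.10 and 0.11.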

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

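The limma-trend test on FPKM was planned, and looking in it at genes without counts was chosen after the results were seen. Genes that only the FPKM files list were outside the comparison of counts, and 293 of them passed the FPKM filter. In 4 of these, signal in both hon45 libraries stood above that in both WT libraries (limma-trend on log2(FPKM + 1), adjusted p under 0.05). The plastid tRNA genes TRNV.1 and TRNS.2 were listed at 0 in both WT libraries and at no less than 609 and 151 FPKM in hon45, where the higher values were 749 and 213. The plastid gene PETG went the other way, with 30.1 and 41.9 FPKM in WT, and was listed at 0 in both hon45 libraries. Other short plastid genes switched between 0 and high values within a genotype: in the order WT 1, WT 2, hon45 1 and hon45 2, TRNS.1 had 201.7, 0, 563.2 and 0 FPKM, PSAI 30.07, 0, 137.9 and 0, PETN 172.7, 0, 0 and 352.5, and ORF31 0, 153.9, 161.2 and 0. A value of 0 in these files can be a failed estimate, so no fold is given and these 3 plastid differences are uncertain. The pseudogenes AT5G35935 and AT4G04410 had at least 2.36 and 2.65 FPKM in hon45, against at most 0.344 and 0.886 FPKM in WT (limma-trend adjusted p = 0.0189 and 0.0359). SADHU3-2, a retroelement-derived pseudogene, was lower, with 3.78 and 3.71 FPKM in WT and 0.274 and 0.281 FPKM in hon45 (limma-trend adjusted p = 0.00561).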

How the results depend on the processing

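Fits without ribosomal RNA, overlapping or low genes, or with a gene-length trend removed, were chosen after the data were seen. Against 1199 called genes, other settings gave 724 (stricter count filter; 345 rose, 379 fell), 325 (adjusted p under 0.01), 107 (log2 fold change of at least 1), and with FPKM 121, 110 (pseudocount 0.1) and 7 (no filter, 4653 at an unadjusted p under 0.05); leaving out 1 library gave 119 to 3836. Stricter thresholds call fewer genes by construction, and a fit with 1 library left out can lose calls by lower power alone. Beyond that the cause was not tested. The remaining settings gave 811 to 1767 genes. The replicate number as a block gave 1767 genes and 9 lists. Same-numbered libraries deviated together by a correlation of 0.0469. With 2 libraries per genotype this cannot exclude a shared batch, and no label says what the number marks. Against 7 lists, 0 passed camera with an estimated correlation (0 at an unadjusted p under 0.05), 1 passed fry (evening clock genes, adjusted p = 0.0106; 5 at an unadjusted p under 0.05), 6 to 11 passed with 1 library left out, and 5 to 10 otherwise. In all, 1194 of the 1199 genes kept their sign without each library in turn, and 89 were called each time (32 rose, 57 fell). Of 45 called named genes, 6 were called under every alternative run for them: HON4, HON5, MRD1, AT1G07887, AT4G06215 and AT4G13577. AT1G07887, AT4G06215 and AT4G13577 have no FPKM value and no length, so the FPKM and length fits were not run for them. AT1G07887 overlaps MRD1 and had nearly the same counts, so these 2 may not be separate results. AT4G06215 had 280, 322, 961 and 599 counts in WT 1, WT 2, hon45 1 and hon45 2. Those of TIFY4A, whose rise is uncertain, were close, at 251, 303, 983 and 508. For the 57 named genes, 916 of 1128 values held, 193 lost and 7 gained a call, and 12 changed sign, none of these past the threshold. AP1 was at 0.0489 (FPKM, no filter) and FUL at −0.0404 (length trend of genes from 5 CPM removed). MAF3 was at 0.015 (FPKM, and FPKM without a filter) and 0.0191 (pseudocount 0.1). With 1 library left out, log2 differences ranged from −0.96 to 0.0764 for TSF, −0.634 to 0.0296 for SOC1, −0.153 to 0.0273 for SVP, −0.236 to 0.163 for MAF3 and −0.691 to 0.654 for FUL; the cause was not tested. Leaving out plastid and mitochondrial genes was not run, since the count table lists 0 of them. What depth limits was not tested; FT had 33 to 68 counts per library.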

Other observations

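All tests in this part were chosen after the results were seen. Genes were also grouped by the letters that open their RefSeq symbol, with 251 families of at least 8 tested genes. The 502 one-sided hypergeometric tests were adjusted by Benjamini-Hochberg. In 100 shuffles of the calls, 1 had a family that passed. Both the tests and the shuffles take genes as independent, so neither allows for members of a family that change together. Both also draw on all 29226 tested genes, although 0 of the 724 rises had a mean under 1 CPM. Expected numbers of rises can therefore be too low for families of well-expressed genes. Genes named EMB, after embryo-defective mutants, stood out, with 25 of 159 higher in hon45 against 3.94 expected (adjusted p = 9.94e-11); emb2726 rose from 47.8 ± 11.7 to 87.8 ± 3.64 CPM and emb1138 from 248 ± 22.1 to 350 ± 21.6 CPM (SD, n = 2). The RPL family had 7 of 23 higher (adjusted p = 0.000161), among them RPL15 from 104 ± 27.8 to 161 ± 6.03 CPM and RPL12-A from 195 ± 48.2 to 283 ± 9.38 CPM, both plastid ribosomal proteins. PTAC genes, named for the plastid transcriptionally active chromosome, had 5 of 14 higher (adjusted p = 0.00192) and CPN genes, chaperonins, 3 of 8 (adjusted p = 0.0484), with CPN60B from 61.3 ± 20.2 to 103 ± 1.87 CPM. UBP genes, ubiquitin-specific proteases, had 5 of 29 higher (adjusted p = 0.0478). With the length trend of genes from 5 CPM and of genes from 1 CPM removed, CPN had adjusted p-values of 0.0185 and 0.643 and UBP of 1 and 0.951. RPL and PTAC genes have median lengths of 629 and 1271 bases, below the 1384 bases of tested genes.

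Lower families were AGP, the arabinogalactan proteins, with 7 of 30 (adjusted p = 0.000106), and RHS (root hair specific) and TIP (tonoplast aquaporins), each with 3 of 9 (adjusted p = 0.0279 for both). AGP3 went from 95.9 ± 11.6 to 58.1 ± 5.98 CPM, RHS13 from 86.3 ± 5.36 to 54.5 ± 1.92 CPM and TIP4;1 from 55.6 ± 5.69 to 42.7 ± 1.42 CPM. With a library left out, EMB had adjusted p-values of 1.37e-05, 6.58e-16, 0.236 and 0.0243 without WT 1, WT 2, hon45 1 and hon45 2. RPL kept its side of 0.05 only without WT replicate 2 (0.0117), CPN likewise (0.00987), and UBP and TIP in no such fit. PTAC and AGP passed without either WT replicate, and RHS without WT replicate 1, while none of these passed without a hon45 library. Fits without a hon45 library called far fewer genes, so a family of few genes could hardly pass in them. Those failures therefore do not show that a family depends on 1 hon45 library. AGP passed with neither length trend removed (0.102 and 1), and RHS and TIP with that of genes from 5 CPM removed (0.00212 and 0.0331) but not with that of genes from 1 CPM removed (0.37 and 1).

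Long genes were higher and short genes lower in hon45, with Spearman's rho from 0.322 to 0.39 over the 4 pairs of a WT and a hon45 library. A length bias that differs between libraries whatever the genotype may be a source, since the WT libraries differed in the same trend (rho 0.24), while the hon45 libraries had a rho of −0.00375 over genes from 5 CPM and of −0.224 over genes from 1 CPM. With 2 libraries per genotype this cannot be told apart from an effect of the mutations on long genes, which was not tested. The trend as the whole cause of the calls is argued against by calls that outlasted its removal. Of 1137 calls with a length, 672 (59.1%) kept call and direction with the trend of genes from 5 CPM removed. They were 334 of 440 falls but only 338 of 697 rises. Lengths were estimated, so some kept calls may still carry the trend, and how much of the calls it explains was not measured. The 73.1% kept with the trend of genes from 1 CPM removed says little, since a rho of 0.233 stayed among genes from 5 CPM. The trend as the whole cause for the EMB family, whose median length is 1840 bases, is argued against by the hypergeometric test. With the trend of genes from 5 CPM removed its adjusted p was 1.19e-05 (15 higher, from 25). With that of genes from 1 CPM removed it was 2.94e-11 (25 higher).

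MRD1, HEI10 and AT1G52100, among the largest changes, lie on chromosome 1, as HON5 does. For HEI10, reads of MRD1 counted for both genes are a candidate explanation: HEI10 lost 35.7 CPM, 92% of the 38.8 CPM lost by MRD1, while its WT FPKM was 2.74% of that of MRD1. A segment of another background carried along with HON5 could also place changes there. Within 2 Mb of HON5, leaving out HON5 and overlapping genes such as MRD1, 4 of 581 genes were called at 2-fold or more, among them AT1G52100 and MBP1, against 66 of 18509 elsewhere (odds ratio 1.94, two-sided Fisher's exact p = 0.164), and near HON4 2 of 765 (odds ratio 0.694); over all calls it was 21 of 581 near HON5 against 791 of 18509 (odds ratio 0.84, Fisher's exact p = 0.53). No clustering was thus shown among the genes that this test could use. It left out MRD1, HEI10 and AT1G07887, and its window ended just past their locus. Other called genes with identifiers close to theirs included AT1G53640 (log2 fold change −1.09), GLL23 (AT1G54010, 0.84), ESP (AT1G54040, −0.85) and AT1G54870 (−1.41). These were picked after their values were seen and were not tested as a group. The explanation stays open with so few genes, and sequence variants were not analysed here.

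Of 19 root markers 5 fell, among them TIP2;3, which is also 1 of the 3 lower TIP genes, and the list passed as lower (camera adjusted p = 0.00149, and adjusted p = 0.642 with an estimated correlation). A lower share of root tissue as the single cause would lower markers by one amount if all were root-only and root parts fell alike. Neither condition was tested here, so unequal changes of the markers leave that cause open. Their log2 fold changes differed more than their SEs allow (Cochran Q of 93.4, p = 3.5e-12 by chi-square with 18 degrees of freedom, approximate since SEs rest on 2 libraries per genotype and genes are not independent replicates), with a weighted mean of −0.26, PYK10 at 0.25 and 12 of 19 below 0. Their shortness as the cause is argued against by the list test, which passed with the trend of genes from 5 CPM removed (camera adjusted p = 0.000873); with that of genes from 1 CPM removed it was 0.0041, which says little. A change in particular root cell types stays open and may depend on 1 library, since the list had an adjusted p of 0.166 without hon45 replicate 1.

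The grouping of the 4 libraries has 3 splits into 2 and 2, too few for a share under 0.05; the genotypes gave 1199 genes, as many as that in 1 split, and the higher of the other 2 splits gave 1. On chromosome 5, from 22062805 to 22170538, 15 of 26 neighbouring tested genes each had 215 to 247 more counts in WT replicate 1 than in WT replicate 2 scaled to the same total, and 9 of the 26 were called lower in hon45. All 9 had far more counts in WT replicate 1 than in any other library. AT5G54410, for 1, had 236, 7, 14 and 3 counts in WT 1, WT 2, hon45 1 and hon45 2. These 9 calls thus rest mainly on 1 WT library and are uncertain as a difference between genotypes. The tRNA gene AT5G32017 (277, 362, 1 and 2 counts) and MIR5643b (282, 356, 7 and 1 counts in WT 1, WT 2, hon45 1 and hon45 2) had nearly equal counts, most of them in WT, with log2 fold changes of −7.61 and −6.27 at means under 5 CPM, and AT5G32017 was listed at 0 FPKM in every library. The lncRNA gene AT2G04005 had 3, 14, 416 and 138 counts in the same order.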
